A study of Mus musculus with 24 samples.

How the data were processed

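Whole tumours were profiled by RNA sequencing, 24 in all, with total RNA extracted in TRIzol and libraries made with the VAHTS Universal V5 kit. The submitters' processing notes credit read trimming, alignment and counting to fastp, HISAT2 and HTSeq on the mouse genome build mm10, without versions, options, annotation or strand setting. Counts of overlapping, antisense or near-identical genes, such as the globin genes and the Saa and Oas families, are uncertain for that reason. The table deposited by the authors holds the raw read count of each gene in each tumour, with no normalization, for 27368 genes given by Entrez identifier and symbol. Each column was checked to hold whole numbers, and column totals ran from 37099055 to 40004502. No 2 tumours of a group were copies of 1 library, since the lowest difference between replicates, a chi-square per gene, was 14.4. Counts of reads without molecular identifiers are not independent molecules, so replicate tumours, not counting error, set the precision of each value.

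Groups were read from the labels in 2 ways, because the written labels (treatment, cell type and batch) and the letters of the coded identifier name different groups for 19 of the 24 tumours. The written batch label repeats the treatment and cell type, so it is no technical batch. Both readings, the 12 comparisons, the gene lists, the rule for named genes and a check of the labels were fixed before the data were examined, with the written label as the main reading. No tumour was moved from one group to another. Replicate numbers follow the order of deposit in the written groups and the number in the identifier in the coded groups, and pair no tumours, so no paired test was run. Counts of genes are given for both readings. Gene values are given for the coded reading, a choice made after the result of the label check was known.

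Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F-tests with TMM scaling on all 24 libraries in 8 groups of 3. The filterByExpr function kept 16560 genes, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Contrasts compared OE with NC in sham and in irradiated tumours, radiation with sham and olaparib with sham in each cell line, and radiation plus olaparib with radiation alone in each cell line. Further contrasts took the radiation effect in OE minus that in NC, and the averages of the cell line, radiation and olaparib effects over 4 strata each. Levels beside fold changes are TMM-scaled CPM, the reads of a gene per 1000000 counted, as mean and SD, and each log2 fold change carries its standard error (SE). The label check used the 2000 most variable genes, a pseudo-F on log2 CPM with a pseudocount of 0.5 and 10000 permutations, and permutation tests with 100000 draws for the p53 target list and for Vmp1. All permutation tests were two-sided except the pseudo-F, which is one-sided by construction.

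Gene lists numbered 41, with 20 pathways, 17 sets of cell type markers and 4 technical checks. Of their entries 811 were found by symbol, 6 by an older symbol and 18 not at all. Each list was tested with limma 3.58.1 camera on voom values at a preset correlation of 0.01, again with a correlation estimated from the libraries, and with fry, adjusting over the lists of a comparison. Lists with fewer than 5 tested members are given as values only. Named genes are up to 10 risen and 10 fallen called genes with the largest fitted change, at a mean of at least 1 CPM and, for contrasts of 2 groups, without overlap between their tumours. The rule left out predicted genes, pseudogenes and receptor segments, and added up to 4 members per list with the smallest p and fixed genes that included Vmp1, Polq, Parp1, Lig3, Pdcd4, Cdkn1a, Mdm2, Ccng1 and Mki67. Some genes that met the rule are not reported here. Vmp1 hosts the miR-21 gene, and the microRNA itself was not analysed here. Gene positions come from the RefSeq annotation, in which 26380 of the Entrez identifiers were found.

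Sites for the miR-21-5p seed were searched in the longest annotated 3' UTR of each gene as ATAAGCT or ATAAGCTA, which covers 95.9% of the tested protein-coding genes. The median log2 fold change of genes with a site was compared with that of genes without, with camera for the test and the other 419 orders of the same 7 bases as controls. Those control sites were chosen after the data were seen.

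Alternatives were DESeq2 1.42.0 size factors, the DESeq2 test, no filter on low counts, a fit on the compared groups alone, additive factors for the averages, and leaving out each library in turn. Chosen after the data were seen were fits without 3 libraries of unlike composition, and without the 1 among them led by collagen genes. So were limma voom fits with sample quality weights, list tests without each of those 3 in turn, and single genes without the collagen-led library. The procedure was tested on simulated data, in which radiation was compared within NC and over 4 strata. It recovered 37.3% and 76.1% of 2-fold changes in those designs, with 2.5% and 7.2% of the calls false. The simulated libraries held no difference in tissue composition and no unlike tumour, so these rates need not hold for the real data. Scripts ran in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.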

Results

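RNA was sequenced from 24 tumours grown under the skin of female C3H mice from SCC7, a mouse squamous cell carcinoma line. The cells carried an empty vector (NC) or overexpressed the microRNA miR-21-5p (OE). Each mouse received about 1000000 cells, and treatment began at a mean tumour volume near 300 cubic millimetres. Treatments were sham, X-rays to the tumour (IR, 8 Gy per day on 3 days), olaparib (50 mg/kg, given 2 h before irradiation), which blocks the PARP enzymes acting at DNA breaks, or both. This makes 8 groups of 3 tumours. The study asks how miR-21-5p bears on radiation resistance and on alternative end joining, an error-prone route of double-strand break repair. Libraries held 37099055 to 40004502 counted reads each, over 27368 genes, of which 16560 were tested.

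Cdkn1a, the p53 target that encodes a cell cycle inhibitor, separated tumours by the letters of their coded identifier and not by their written treatment. Before TMM scaling its level was 370 to 777 CPM in the 12 tumours coded as irradiated and 171 to 345 CPM in the 12 others. After TMM scaling the lowest of the tumours coded as irradiated lay below the highest of the others. Under the written label the ranges overlapped, with 229 to 777 CPM in 12 irradiated and 171 to 767 CPM in 12 unirradiated tumours. Mki67, a proliferation marker, lay at 17.4 to 423 CPM in tumours coded as irradiated and at 316 to 463 CPM in the rest. The written label and the code name the same group for 5 tumours and different groups for 19, of which 8 differ in cell line, 8 in radiation and 16 in olaparib. In the check of the labels, mean log2 CPM of the p53 target list was 0.484 higher in coded irradiated tumours (permutation p = 1.0e-05, the smallest these permutations can give) and 0.215 higher in written ones (permutation p = 0.074). The 8 coded groups gave a pseudo-F of 1.90 (permutation p = 0.011), the 8 written groups 1.40 (permutation p = 0.099). Radiation by code gave a pseudo-F of 6.74 (permutation p = 0.0001, the smallest possible), against 2.59 (permutation p = 0.032) for the written label. Neither reading separated OE from NC by Vmp1, the host gene of miR-21, with differences of -0.125 (permutation p = 0.25) by code and -0.049 (permutation p = 0.66) by the written label. A host gene does not show a microRNA made from a vector, so Vmp1 tests neither the overexpression nor the labels of cell line. Comparisons are detailed for the coded reading, and the count under the written label stands beside each.

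**Figure D1:**
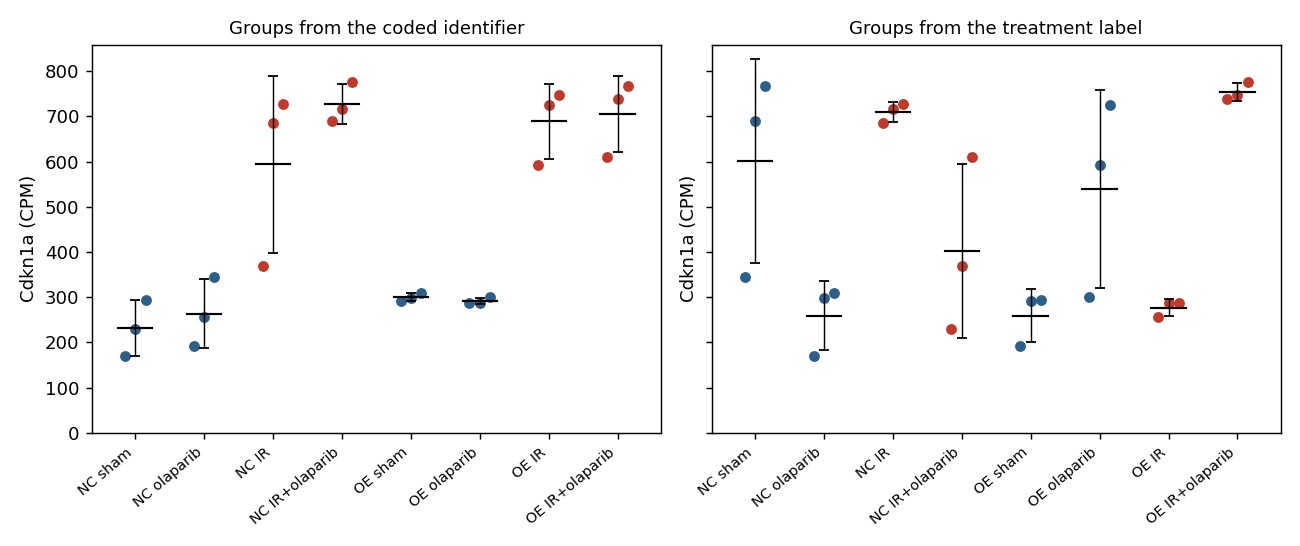
Cdkn1a in CPM, reads of the gene per 1000000 counted, before TMM scaling, for each of 24 tumours (points), with the mean and SD of each group of 3, grouped by the coded identifier on the left and by the written label on the right; red marks groups named as irradiated, blue the others. By code the 12 irradiated tumours lie at 370 to 777 CPM and the others at 171 to 345 CPM, and by the written label the ranges overlap.

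Radiation by code, averaged over both cell lines and both olaparib settings (12 tumours against 12), went with higher levels of p53 target genes. The coded reading was detailed after a label check that used this list. The p-values of p53 targets by code, here and below, are therefore no independent evidence of a radiation effect. Those of other genes and lists for radiation by code are likewise not independent of that choice of reading. Cdkn1a (Entrez 12575, chromosome 17, 29090979 to 29100722, mm10) stood at 690 ± 122 CPM after radiation and 268 ± 46.0 CPM without it. Its log2 fold change was 1.36 ± 0.12 (edgeR adjusted p = 1.62e-06), and 11 of 12 irradiated tumours lay above every unirradiated one. Mdm2, the ubiquitin ligase that degrades p53 (Entrez 17246, chromosome 10, 117688875 to 117710758), rose by 1.17 ± 0.19 on the log2 scale (adjusted p = 0.00029). Ccng1, cyclin G1 (Entrez 12450, chromosome 11, 40748552 to 40755309), rose by 0.94 ± 0.10 (adjusted p = 6.24e-06), as did the death receptor gene Fas by 1.49 ± 0.17 and Phlda3 by 0.75 ± 0.08. Of 37 tested p53 targets 23 rose and 1 fell, with the same counts adjusted over the list alone, and the median log2 fold change was 0.46. The list passed camera (adjusted p = 3.71e-07), with adjusted p = 0.295 with an estimated correlation. In the apoptosis list, which shares Fas, 5 of 23 members rose and 3 fell (camera adjusted p = 0.92).

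Genes of cell division and DNA repair were lower after radiation, and a fall of repair genes beyond that of cell division genes was not tested. Mki67 (Entrez 17345, chromosome 7, 135689784 to 135716450) fell from 416 ± 27.1 to 176 ± 103 CPM, a log2 fold change of -1.27 ± 0.29 (adjusted p = 0.00303). Of 34 DNA replication genes 33 fell, and all 34 when adjusted over the list alone, with a median of -0.91; examples are E2f2 at -1.43 ± 0.20 and the clamp loader subunits Rfc4 at -0.99 ± 0.16 and Rfc5 at -1.02 ± 0.17. Among 34 mitosis genes 27 fell, and 34 adjusted over the list alone, including the kinase gene Aurkb at -1.27 ± 0.26 and the cyclin gene Ccna2 at -1.33 ± 0.32. Camera gave adjusted p = 7.49e-16 for replication and adjusted p = 7.23e-12 for mitosis, against adjusted p = 0.406 and adjusted p = 0.479 with an estimated correlation. Alternative end joining fell in 16 of 19 genes, the same 16 in number adjusted over the list alone, with a median of -0.38 (camera adjusted p = 2.16e-07, adjusted p = 0.406 with an estimated correlation). Its polymerase gene Polq (Entrez 77782, chromosome 16, 37011741 to 37095419) went from 11.2 ± 1.68 to 5.60 ± 3.16 CPM, at -1.03 ± 0.28 (adjusted p = 0.00826). Lig3, the ligase of the pathway (Entrez 16882, chromosome 11, 82781109 to 82804274), was at -0.49 ± 0.09 (adjusted p = 0.000892). Parp1, the break sensor that olaparib inhibits (Entrez 11545, chromosome 1, 180568891 to 180600999), was at -0.61 ± 0.12 (adjusted p = 0.00139).

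Other repair lists fell in most members, classical end joining in few. Homologous recombination fell in 20 of 25 genes (21 adjusted over the list alone), with Brca2 at -1.13 ± 0.22 and Rad51ap1 at -1.15 ± 0.27 (camera adjusted p = 6.73e-09, adjusted p = 0.406 with an estimated correlation). The Fanconi anaemia pathway, which repairs crosslinks, fell in 9 of 15 genes (10 adjusted over the list alone), with Fancl at -0.62 ± 0.11 (camera adjusted p = 3.86e-05, adjusted p = 0.406 with an estimated correlation). Checkpoint genes fell in 11 of 13, Timeless at -0.82 ± 0.15 and Tipin at -0.79 ± 0.15 among them (camera adjusted p = 1.31e-05, adjusted p = 0.406 with an estimated correlation). In base excision repair 9 of 14 genes fell and 2 rose, with the glycosylase genes Neil3 at -2.03 ± 0.33 and Tdg at -0.83 ± 0.12 (camera adjusted p = 0.000735, adjusted p = 0.406 with an estimated correlation). Of 18 classical end joining genes 1 rose, the nuclease gene Dclre1c at 0.64 ± 0.15, and 3 fell, Xrcc6, which encodes Ku70, at -0.66 ± 0.17 among them (camera adjusted p = 0.454).

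**Figure D2:**
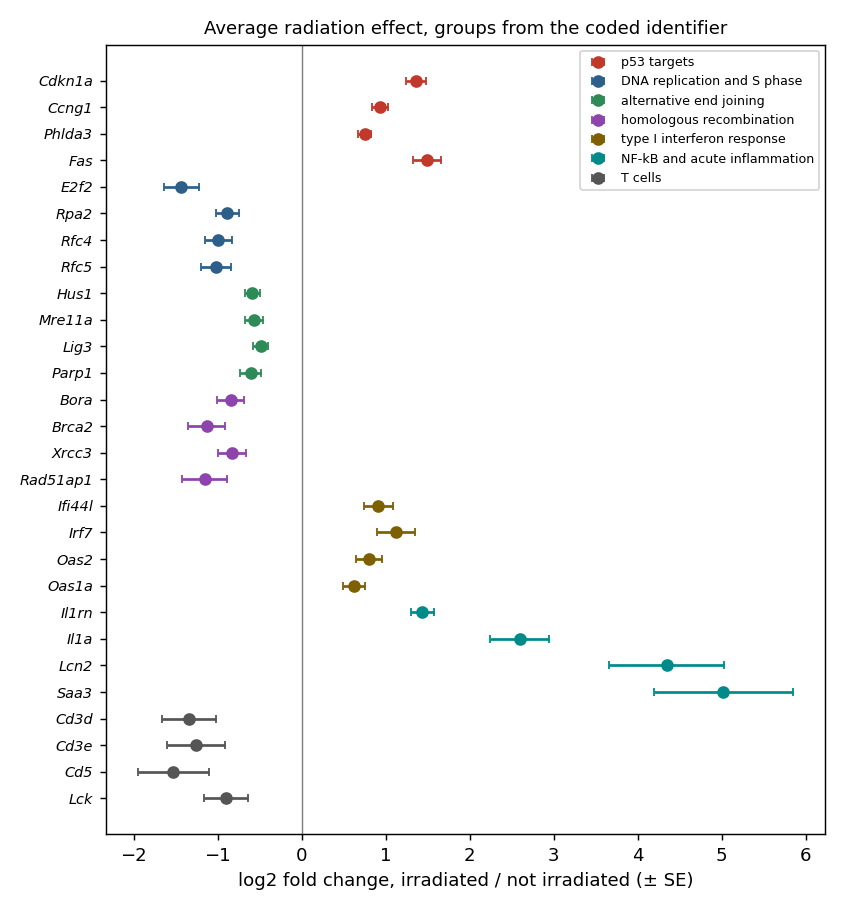
Log2 fold change of irradiated over unirradiated tumours by code, averaged over 4 strata (points, 12 tumours against 12), with bars of 1 SE, for the 4 members with the smallest p of each of 7 gene lists, coloured by list. The p53 targets, type I interferon and NF-kB genes shown lie above 0, from 0.62 for Oas1a to 5.02 for Saa3, and the replication, repair and T cell genes shown lie between -0.49 and -1.53.

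Inflammatory, interferon and myeloid genes rose with radiation. The acute-phase genes Saa3 and Lcn2 rose by 5.02 ± 0.82 and 4.35 ± 0.68 on the log2 scale, and the cytokine genes Il1a and Il1rn by 2.59 ± 0.35 and 1.44 ± 0.14. Without OE IR+olaparib replicate 2 by code Saa3 was at 3.33 and Lcn2 at 3.64, both still called. In the NF-kB and acute inflammation list 17 of 23 genes rose and none fell, or 17 and 1 adjusted over the list alone (camera adjusted p = 2.74e-05, adjusted p = 0.436 with an estimated correlation). Type I interferon response genes rose in 21 of 32, over all genes and adjusted over the list alone, among them the antiviral regulator Irf7 at 1.12 ± 0.22 and Oas2 at 0.80 ± 0.16. That list had a median of 0.56 and 32 of 32 members above 0 (camera adjusted p = 1.11e-07, adjusted p = 0.479 with an estimated correlation). Neutrophil markers rose in 11 of 14, with S100a8 at 3.73 ± 0.69 and the collagenase gene Mmp8 at 3.23 ± 0.48 (camera adjusted p = 0.0061, adjusted p = 0.436 with an estimated correlation). Macrophage and monocyte markers rose in 13 of 21, with Apoe at 1.98 ± 0.37 and Lyz2 at 1.03 ± 0.23, while 1, the chemokine receptor gene Cx3cr1, fell from 200 ± 70.8 to 41.6 ± 45.9 CPM (camera adjusted p = 0.00351, adjusted p = 0.535 with an estimated correlation). Senescence-associated secretion genes rose in 13 of 21 and fell in 3, with the stress cytokine gene Gdf15 at 3.06 ± 0.39 and Mmp10 at 2.51 ± 0.37 (camera adjusted p = 0.00283, adjusted p = 0.406 with an estimated correlation). Adjusted over the list alone, 11 neutrophil, 15 macrophage and 14 senescence genes rose.

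T cell genes were lower after radiation. The receptor chain genes Cd3d and Cd3e were at -1.34 ± 0.32 and -1.26 ± 0.34, and Cd5 and the kinase gene Lck at -1.53 ± 0.42 and -0.90 ± 0.26. In all 9 of 19 T cell markers fell (12 adjusted over the list alone), and camera gave adjusted p = 0.000735, against adjusted p = 0.583 with an estimated correlation. Dendritic cell markers went both ways, with 7 of 16 falling and 3 rising (camera adjusted p = 0.0588). Siglech, a marker of plasmacytoid dendritic cells, was at -4.00 ± 0.51 and Clec9a at -2.23 ± 0.53, and the lectin gene Clec10a at 1.65 ± 0.37. Of 18 cytotoxic cell genes 4 rose and 3 fell, with Gzmc at 2.37 ± 0.50 and Pdcd1 at -1.15 ± 0.32 (camera adjusted p = 0.881). Mast cell markers rose in 3 of 8 (7 adjusted over the list alone, camera adjusted p = 0.0314, adjusted p = 0.667 with an estimated correlation), at camera adjusted p = 0.0582 without OE IR+olaparib replicate 2 and 0.0736 without NC sham replicate 3. B and plasma cell markers rose in 1 of 13, Cd22 at 1.44 ± 0.27 (camera adjusted p = 0.838). Of the interferon gamma and antigen presentation list 6 of 32 genes rose, Ido1 at 1.34 ± 0.28 and Cd274, which encodes PD-L1, at 1.12 ± 0.27 (camera adjusted p = 0.23). The list of cGAS-STING genes and chemokines had 3 of 14 risen and 2 fallen, with the DNA sensor gene Ifi204 at 0.66 ± 0.10 and Ccl5 at -0.94 ± 0.24 (camera adjusted p = 0.315).

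Genes of lipid synthesis were among those that fell most. The cholesterol synthesis enzymes Cyp51, Fdps and Sqle were at -2.48 ± 0.25, -2.41 ± 0.21 and -2.29 ± 0.29, and the fatty acid desaturase gene Fads2 at -2.38 ± 0.34. For each of these 4 genes all 12 irradiated tumours lay below every unirradiated one. Hypoxia response genes fell in 17 of 26 and rose in 1, with the glycolytic genes Pdk1 at -1.02 ± 0.13 and Ldha at -0.83 ± 0.13 and the hypoxia-induced gene Ankrd37 at -1.38 ± 0.24 (camera adjusted p = 3.04e-06, adjusted p = 0.406 with an estimated correlation). Ribosomal protein genes fell in 19 of 20, with Rpl3 at -0.71 ± 0.10 (camera adjusted p = 2.48e-09, adjusted p = 0.41 with an estimated correlation). Oxidative phosphorylation genes fell in 12 of 20, with Atp5a1 at -0.32 ± 0.07 (camera adjusted p = 0.000162, adjusted p = 0.488 with an estimated correlation). In the oxidative stress and NRF2 list 6 of 19 rose and 2 fell, with the ferritin gene Ftl1 at 0.72 ± 0.15 (camera adjusted p = 0.498). The median over all tested genes was 0.041.

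Some markers of neighbouring tissue were higher after radiation, and several of these calls rested on single tumours. Skeletal muscle genes rose in 14 of 22 (18 adjusted over the list alone), with Des at 2.93 ± 0.73 and the sarcomere gene Ttn at 1.63 ± 0.54 (camera adjusted p = 0.0243, adjusted p = 0.79 with an estimated correlation). Trim63, a ubiquitin ligase of muscle, had 79.6 ± 268 CPM after radiation and 0.829 ± 1.05 CPM without it, and its log2 fold change of 3.93 was 2.40 without NC IR replicate 1 and no longer called without OE IR+olaparib replicate 2. Without OE IR+olaparib replicate 2 by code 2 of the 22 muscle genes rose (median 1.03 in place of 2.39, camera adjusted p = 0.123), without NC IR replicate 1 it was 1 and without NC sham replicate 3 it was 5. The muscle list took 2.154% of counts in NC IR replicate 1 and 0.529% in OE IR+olaparib replicate 2. Fibroblast markers rose in 10 of 20 (11 adjusted over the list alone), with the matrix gene Dcn at 1.85 ± 0.33 (camera adjusted p = 0.0504), and in OE IR+olaparib replicate 2 the collagen gene Col3a1 alone took 3.51% of counts. Without that tumour 7 fibroblast markers rose and 3 fell (median 0.30 in place of 1.06, camera adjusted p = 0.353). Adipocyte markers rose in 6 of 13 (camera adjusted p = 0.0125, adjusted p = 0.667 with an estimated correlation) and Schwann cell markers in 7 of 11 (camera adjusted p = 0.00412, adjusted p = 0.488 with an estimated correlation). Endothelial markers rose in 6 of 17 (camera adjusted p = 0.122), pericyte markers in 3 of 10 (camera adjusted p = 0.808) and keratinocyte differentiation genes in 5 of 19 (camera adjusted p = 0.226). Without OE IR+olaparib replicate 2 by code 4 Schwann cell markers rose, and 4 endothelial markers rose and 3 fell. Squamous basal genes rose in 2 of 16 and fell in 3 (camera adjusted p = 0.92), and no erythroid gene of 7 was called by edgeR (camera adjusted p = 0.352). Of 4 hair follicle genes 2 rose and 1 fell, and Xist, a sex-linked gene, was at 0.48 ± 0.20 (adjusted p = 0.0596).

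Immediate early genes, which can also respond to the handling of tissue, rose in 11 of 14, with Fos at 1.86 ± 0.44 and Dusp1 at 1.77 ± 0.41 (camera adjusted p = 0.00215, adjusted p = 0.535 with an estimated correlation). TGF-beta response genes rose in 7 of 21 and fell in 1 (camera adjusted p = 0.386), and without OE IR+olaparib replicate 2 by code 1 rose and 4 fell, and 4 rose and 1 fell without NC IR replicate 1. In the epithelial-mesenchymal transition list 7 of 21 rose, Zeb2 by 0.62 ± 0.14 among the mesenchymal genes and Cdh1 by 1.27 ± 0.36 among the epithelial ones (camera adjusted p = 0.352). Of 40 literature targets of miR-21-5p 11 rose and 5 fell, with Rhob at 0.96 ± 0.14 (camera adjusted p = 0.342). In all 6483 genes were called by edgeR, 3586 higher and 2897 lower after radiation, and 5504 to 7540 with any 1 library left out. With the written groups the same contrast called 1 gene by edgeR (5099 at an unadjusted p under 0.05, 2502 by DESeq2), the splicing factor gene Snrpe at -0.63 ± 0.09 (adjusted p = 0.0303), and Cdkn1a was at 0.39 ± 0.19 (adjusted p = 0.165). That count of 1 was 0 without 1 library of written OE sham (replicate 1 or 2), OE IR+olaparib (1 or 2), OE IR (1 or 3), OE olaparib (1 or 3), NC IR (1, 2 or 3) or NC olaparib (3). It was 2752, 1946 and 844 without written NC IR+olaparib replicates 2, 3 and 1, 2018 without NC sham replicate 1, 1060 without OE olaparib replicate 2, 435 without OE IR replicate 2, 397 without OE IR+olaparib replicate 3, 77 and 8 without NC olaparib replicates 1 and 2, and 2 without OE sham replicate 3.

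**Figure D3:**
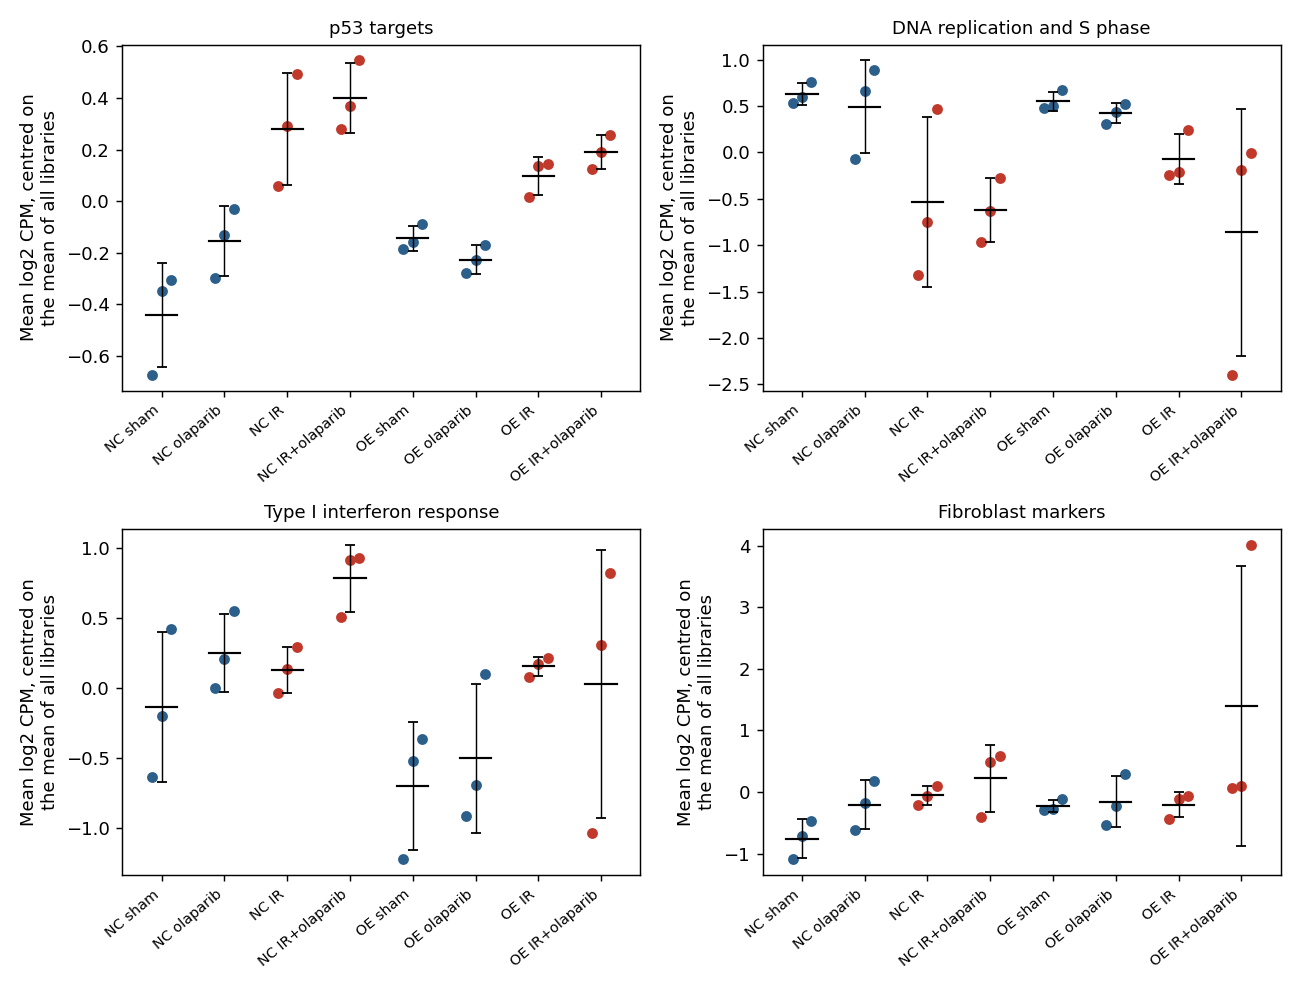
Mean log2 CPM over the genes of 4 lists, centred on the mean of all 24 libraries, for each tumour (points) in the 8 coded groups, with group mean and SD (n = 3), red for irradiated and blue for unirradiated groups. p53 targets are higher and replication genes lower in irradiated groups, and 1 tumour of the OE IR+olaparib group stands far above the others in fibroblast markers.

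In NC tumours given radiation alone, p53 targets rose and replication and ribosomal genes fell, beside a gain of muscle genes that was largest in 1 tumour. Cdkn1a went from 242 ± 52.6 to 585 ± 220 CPM (n = 3 each), a log2 fold change of 1.28 ± 0.24 (edgeR adjusted p = 0.0139), and Ccng1 and Mdm2 were at 1.05 ± 0.19 and 1.25 ± 0.38. Of 37 p53 targets 11 rose (16 adjusted over the list alone, camera adjusted p = 4.48e-06, adjusted p = 0.521 with an estimated correlation). Replication genes fell in 12 of 34 (27 adjusted over the list alone, camera adjusted p = 8e-15, adjusted p = 0.624 with an estimated correlation) and ribosomal protein genes in 19 of 20 (camera adjusted p = 1.22e-13, adjusted p = 0.521 with an estimated correlation). The largest falls included Cx3cr1, from 167 ± 8.63 to 8.21 ± 7.44 CPM, the retinoid-binding protein gene Crabp1 at -2.71 ± 0.51, the lectin gene Mgl2 at -2.55 ± 0.75, Fdps at -2.73 ± 0.43 and Cyp51 at -2.35 ± 0.50. The 10 largest rises included genes of striated muscle or its metabolism, such as Trim63, at 313 ± 534 against 0.0794 ± 0.0423 CPM, Pdk4, at 215 ± 355 against 0.0881 ± 0.0516 CPM, and Actn3, at 450 ± 742 against 0.643 ± 0.487 CPM. Lrrc30, Kcnc4 and Acsl6 were at 0 in all 3 sham tumours, so no fold is given for them. The muscle list rose in 5 of 22 genes (17 adjusted over the list alone, camera adjusted p = 0.000472, adjusted p = 0.736 with an estimated correlation). Alternative end joining fell in 1 of 19 genes (camera adjusted p = 3.72e-05, adjusted p = 0.624 with an estimated correlation), and Polq was at -0.72 ± 0.55 (adjusted p = 0.394).

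Single tumours carried much of this. NC sham replicate 3, in which the 50 highest genes took 17.16% of counts, had the highest ribosomal level of the 24 tumours (0.836 on the centred mean log2 CPM of the list, against 0.268 and 0.068 in the other NC sham tumours) and the lowest p53 target level (-0.674, against -0.308 and -0.347). Without it the median moved from -0.84 to -0.48 for ribosomal genes (camera adjusted p = 1.71e-09, adjusted p = 0.628 with an estimated correlation), from 0.57 to 0.36 for p53 targets (camera adjusted p = 6.44e-05, adjusted p = 0.503 with an estimated correlation) and from -1.17 to -1.12 for replication genes (camera adjusted p = 2.79e-14, adjusted p = 0.628 with an estimated correlation). Without it edgeR called 0 members of these 3 lists over all genes, and adjusted over the list alone 16, 12 and 0. Without NC IR replicate 1 edgeR likewise called 0 of them over all genes, 20, 11 and 0 adjusted over the list alone, and the muscle median moved from 6.36 to 2.57. The muscle level was 4.389 in NC IR replicate 1, -0.052 and 0.602 in replicates 2 and 3, and -2.889 to -1.464 in the NC sham tumours. Cdkn1a and Ccng1 lost their calls without NC IR replicate 1 or NC sham replicate 3. Mdm2 kept its call only without NC IR replicate 3 of the 6 compared libraries. NC IR replicate 3 lay in or above the range of the tumours coded as unirradiated for Polq, Mki67 and the replication list, with Polq at 14.69 CPM before TMM scaling, the highest of the 24 tumours (1.84 and 4.03 in the other NC IR tumours), Mki67 at 423.10 CPM (70.34 and 116.41) and a replication level of 0.466 (-1.323 and -0.746). Its Cdkn1a, at 369.60 CPM before TMM scaling, was the lowest of the tumours coded as irradiated and above all those coded as unirradiated. After TMM scaling it lay below NC olaparib replicate 2, which had 344.64 CPM before scaling (TMM factors 1.114 and 1.009). Without NC IR replicate 3 Polq was called at -1.85 ± 0.53 (adjusted p = 0.021), Parp1 at -1.08 ± 0.24 (adjusted p = 0.00564) and Mki67 at -2.10 ± 0.59 (adjusted p = 0.0201). Polq was at -0.31 without NC IR replicate 1 and -0.43 without NC IR replicate 2. This NC contrast called 1659 genes, 764 higher and 895 lower. The count was 2 without NC IR replicate 1 (2.154% muscle reads), 3 without NC sham replicate 3, 271 without NC sham replicate 1, 269 without NC IR replicate 2 and 3733 without NC IR replicate 3. Libraries of other groups, which share the estimate of spread, moved it to 3856 (without OE IR+olaparib replicate 2), 1004 (NC IR+olaparib replicate 3), 1048 (OE IR replicate 2), 1031 (OE olaparib replicate 1) and 998 (OE IR replicate 1). By the written label 5 genes were called, the kynurenine transaminase gene Kyat1 at 2.15 ± 0.36, the autophagy gene Uvrag at 1.12 ± 0.18, Gclc, which makes glutathione, at 0.90 ± 0.14, the helicase gene Fbh1 at 0.86 ± 0.15 and Ppp1r21 at 0.79 ± 0.12, and Cdkn1a was at 0.26 ± 0.37 (adjusted p = 0.744). Those 5 calls became 1101 without written NC IR+olaparib replicate 1, 14 without OE IR+olaparib replicate 1, 10 without NC olaparib replicate 2 and 3 without NC olaparib replicate 1. They became 0 without 1 library of written OE sham (any replicate), OE IR (any), NC IR (any), NC sham (2 or 3), OE IR+olaparib (2), OE olaparib (1) or NC olaparib (3).

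In OE tumours radiation alone raised Cdkn1a and Il1rn and lowered Hmgcs1. Cdkn1a went from 290 ± 8.22 to 700 ± 86.0 CPM (n = 3 each), at 1.27 ± 0.24 (edgeR adjusted p = 0.0316). The interleukin-1 antagonist gene Il1rn was at 1.98 ± 0.28, the costimulatory ligand gene Tnfsf4 at 3.66 ± 0.71, the growth factor gene Btc at 3.61 ± 0.68, the stem cell receptor gene Lgr6 at 3.67 ± 0.64, Ecm1 at 2.07 ± 0.36 and the drug transporter gene Abcb1a at 1.69 ± 0.29. Among genes that fell were Hmgcs1, an enzyme of the mevalonate pathway, at -1.45 ± 0.29, Insig1, which restrains sterol synthesis, at -1.24 ± 0.22, and the zinc finger gene Zfp606 at -1.23 ± 0.23. The NF-kB and acute inflammation list rose in 1 of 23 genes (6 adjusted over the list alone), with a median of 1.52 (camera adjusted p = 2.16e-06, adjusted p = 0.472 with an estimated correlation). The type I interferon list had 0 of 32 genes called by edgeR (5 adjusted over the list alone), a median of 0.90 and 32 of 32 members above 0 (camera adjusted p = 1.8e-13, adjusted p = 0.472 with an estimated correlation). Of 37 p53 targets 1 rose (11 adjusted over the list alone, camera adjusted p = 0.00057, adjusted p = 0.472 with an estimated correlation). In all 41 genes were called, 30 higher and 11 lower, and under the written label 0 by edgeR (238 at an unadjusted p under 0.05, 2 by DESeq2). The count was 0 without OE IR replicate 1, OE sham replicate 2 or OE sham replicate 3, 1 without OE sham replicate 1, 2 without OE IR replicate 2 and 136 without OE IR replicate 3. Cdkn1a stayed called only in the last of these 6 fits. With libraries of other groups left out it was 397 (OE IR+olaparib replicate 2), 288 (NC IR replicate 3), 98 (NC sham replicate 3), 26 (NC sham replicate 1), 22 (OE olaparib replicate 1), 21 (NC IR+olaparib replicate 3), 21 (NC olaparib replicate 3) and 14 (OE olaparib replicate 3).

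Whether miR-21-5p altered the response to radiation was tested as the radiation effect in OE minus that in NC. Cdkn1a differed by 0.00 ± 0.34 (edgeR adjusted p = 0.998), Polq by -0.11 ± 0.78, Parp1 by 0.26 ± 0.35 and Lig3 by -0.08 ± 0.26. Without NC IR replicate 3 these were -0.26 ± 0.27, 1.03 ± 0.67, 0.66 ± 0.31 and 0.17 ± 0.25 (adjusted p = 0.581, 0.37, 0.217 and 0.721). Polq and Lig3 thus changed direction. Polq was at -0.52 without NC IR replicate 1, -0.40 without NC IR replicate 2 and -0.28 without OE IR replicate 3. Parp1 was at 0.11, 0.08 and 0.09 in these fits. Lig3 was at 0.12 without NC sham replicate 3. Pdcd4, a known target of miR-21, differed by -1.33 ± 0.57 (adjusted p = 0.234). Its OE against NC value was 0.39 ± 0.40 in sham and -0.94 ± 0.40 in irradiated tumours, so the higher sham level in OE enters this difference. By edgeR 0 genes were called (2992 at an unadjusted p under 0.05, 603 by DESeq2), and under the written label also 0 (819 and 7). The count was 737 without OE IR+olaparib replicate 2, and 1 without OE IR replicate 3, NC IR+olaparib replicate 1 or NC IR+olaparib replicate 2. Of genes called higher in NC, 66.9% were also above 0 in OE, and of those called lower 73.7% were below 0. Across genes, which are not independent replicates, the fold changes of the cell lines had a Pearson r of 0.14. Genes called higher in both numbered 9 (1.38 expected of independent lists) and lower in both 3 (0.59 expected).

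OE tumours, averaged over the 4 treatments (12 against 12), differed from NC tumours in 75 genes by edgeR, some of which are named here. The stromelysin gene Mmp10 rose from 3.09 ± 3.23 to 17.4 ± 16.4 CPM, at 2.26 ± 0.37 (edgeR adjusted p = 0.0121). Inhba, a subunit of activin (Entrez 16323, chromosome 13, 16004256 to 16031609), was at 1.03 ± 0.20 (adjusted p = 0.0355), with 10 of 12 OE tumours above every NC tumour. Pmepa1, which TGF-beta induces (Entrez 65112, chromosome 2, 173224458 to 173276731), was at 0.99 ± 0.19 (adjusted p = 0.0305). The laminin gene Lamb3 rose by 1.25 ± 0.23, the urokinase gene Plau by 0.82 ± 0.16 and the lymphangiogenic factor gene Vegfc by 0.84 ± 0.17. Genes lower in OE included the plakin gene Ppl at -2.16 ± 0.38, the natural killer receptor gene Klrb1c at -1.45 ± 0.28, the potassium channel gene Kcnh1 at -2.40 ± 0.48 and Angptl7 at -1.51 ± 0.30. Over the 24 fits that each left out 1 library Mmp10 kept its call in all, while Ppl lost it in 1, Lamb3 in 4, Pmepa1 in 9, Klrb1c and Kcnh1 in 13 each, Vegfc in 15, Angptl7 in 17 and Inhba in 18.

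By list, TGF-beta response genes rose in 2 of 21 (10 adjusted over the list alone), with a median of 0.75 (camera adjusted p = 1.28e-07, adjusted p = 0.458 with an estimated correlation). Senescence-associated secretion rose in 2 of 21 (7 adjusted over the list alone, camera adjusted p = 4.19e-06, adjusted p = 0.292 with an estimated correlation). The type I interferon list fell in 1 of 32 genes, the antiviral synthetase gene Oas2 at -0.74 ± 0.16 (16 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 7.88e-14, adjusted p = 0.609 with an estimated correlation). Cytotoxic cell genes fell in 1 of 18 (2 adjusted over the list alone, camera adjusted p = 2.51e-07, adjusted p = 0.458 with an estimated correlation). Fibroblast markers had a median of 0.91 with no member called over all genes and 2 adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.995 with an estimated correlation). The collagen-led tumour, OE IR+olaparib replicate 2, carried this, since its fibroblast level was 4.020, against -0.536 to 0.297 in the other 11 OE and -1.090 to 0.578 in the 12 NC tumours. Without NC sham replicate 3 the list was at camera adjusted p = 0.0741. Without the collagen-led tumour the fibroblast median was 0.03 (camera adjusted p = 0.428) and that of TGF-beta response genes 0.27, with 4 of 21 rising (camera adjusted p = 0.000282, adjusted p = 0.305 with an estimated correlation). The senescence median was then 0.25, with 3 of 21 rising (camera adjusted p = 7.2e-05, adjusted p = 0.305 with an estimated correlation), and the type I interferon median -0.38, with 3 of 32 falling (camera adjusted p = 2.27e-08, adjusted p = 0.859 with an estimated correlation). Without NC IR replicate 1 TGF-beta response and senescence genes rose in 1 of 21 each and edgeR called 0 interferon genes (16 adjusted over the list alone), and without NC sham replicate 3 senescence genes rose in 1. The alternative end joining genes were not called, with Polq at 0.06 ± 0.28, Parp1 at 0.08 ± 0.12 and Lig3 at 0.04 ± 0.09 (adjusted p = 0.949, 0.804 and 0.889). Without NC IR replicate 3 Polq was at 0.34, Parp1 at 0.18 and Lig3 at 0.10, and Polq changed sign without NC IR replicate 1 or OE IR+olaparib replicate 3. Pdcd4 (Entrez 18569, chromosome 19, 53892231 to 53937592), a known miR-21 target, was at -0.15 ± 0.20 (adjusted p = 0.759). Vmp1 (Entrez 75909, chromosome 11, 86583858 to 86683836) was at -0.13 ± 0.11 (adjusted p = 0.583), a value that does not bear on miR-21-5p made from a vector.

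The average called 75 genes, 36 higher and 39 lower in OE, and 0 under the written label by edgeR (2851 at an unadjusted p under 0.05, 468 by DESeq2). The written count was 282 without written NC IR+olaparib replicate 2, 134 without OE IR+olaparib replicate 1 and 1 without OE olaparib replicate 2. Single libraries moved the coded count. It was 838 without OE IR+olaparib replicate 2 and 406 without NC IR replicate 3. It was 15 and 24 without OE olaparib replicates 1 and 3, 21, 19 and 27 without OE sham replicates 1, 2 and 3, and 28, 27 and 28 without OE IR replicates 1, 2 and 3. Without NC sham replicates 1 and 2 it was 38 and 22, without NC IR replicates 1 and 2 it was 37 and 28, without NC olaparib replicates 1 and 2 it was 26 and 37, and without NC IR+olaparib replicates 1 and 3 it was 25 and 23.

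Genes with a seed site for miR-21-5p did not pass the test for lower levels in OE tumours by code. Over the 1136 genes with a site the median log2 fold change in sham tumours was 0.230 above that of 12930 genes without (camera adjusted p = 2.9e-08, p = 0.00151 with an estimated correlation). Of 419 control orders of the same bases 374 gave a difference as low, from 0.111 to 0.273. In irradiated tumours the difference was -0.028 (camera adjusted p = 0.59, 43 of 419 controls as low), and over the 4 treatments 0.041 (camera adjusted p = 0.063, 350 of 419). With written groups the differences were -0.022, 0.032 and -0.005 (camera adjusted p = 0.913 each).

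Between sham tumours alone edgeR called 0 genes for OE against NC (2065 at an unadjusted p under 0.05, 376 by DESeq2), and under the written label also 0 (1619 and 84). Ccng1 was at 0.54 ± 0.19 (adjusted p = 0.253) and Pdcd4 at 0.39 ± 0.40 (adjusted p = 0.722), with all 3 OE tumours above every NC tumour for Pdcd4. The lists with the smallest p were type I interferon at a median of -0.78 and interferon gamma at -0.75 (camera adjusted p = 8.07e-08 and 7.43e-07, both adjusted p = 0.738 with an estimated correlation). The count was 23 without OE IR+olaparib replicate 2 by code, and 210 under the written label without NC IR+olaparib replicate 1, which is the same tumour.

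Among tumours given radiation alone, Plau and Timp1 were higher in OE than in NC. Plau was at 282 ± 24.7 against 81.5 ± 25.1 CPM (n = 3 each), a log2 fold change of 1.79 ± 0.33 (edgeR adjusted p = 0.0465), and Timp1, the inhibitor of matrix metalloproteinases, at 173 ± 53.3 against 57.6 ± 6.37 CPM, 1.59 ± 0.25 (adjusted p = 0.0197). The carboxypeptidase gene Cpd was at 0.93 ± 0.14 and the long noncoding RNA Morrbid, known from myeloid cell survival, at 1.35 ± 0.23. Lower were Rin3, a Rab5 exchange factor gene, at -1.50 ± 0.20 (adjusted p = 0.0106), Btbd2 at -0.80 ± 0.13, Zfp646 at -0.61 ± 0.10 and the keratinocyte signalling gene Card14 at -3.67 ± 0.69. Senescence-associated secretion rose in 2 of 21 (3 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.964 with an estimated correlation), and TGF-beta response in 0 by edgeR and 5 adjusted over the list alone (camera adjusted p = 0.0175, adjusted p = 0.964 with an estimated correlation). Polq was at 0.10 ± 0.55, Parp1 at 0.17 ± 0.25 and Pdcd4 at -0.94 ± 0.40 (adjusted p = 0.932, 0.737 and 0.228). The value of Polq rested on single tumours, at 1.23 without NC IR replicate 3, -0.33 without NC IR replicate 1, and below 0 also without NC IR replicate 2 or OE IR replicate 3. Parp1 was at 0.57 and 0.01 without NC IR replicates 3 and 1. The contrast called 14 genes, 10 higher and 4 lower (3092 at an unadjusted p under 0.05). It called 989 without OE IR+olaparib replicate 2, 677 without NC IR replicate 3, 28 without NC olaparib replicate 2, 0 without OE IR replicate 2 or NC IR replicate 1, 1 without NC IR replicate 2, 2 without OE IR replicate 1 and 4 without OE IR replicate 3. It called 5 without NC IR+olaparib replicate 3, 8 without OE olaparib replicate 3 or OE sham replicate 2, and 9 without OE olaparib replicate 1 or 2, NC olaparib replicate 1 or 3 or OE sham replicate 3.

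The written label gave another picture of OE against NC after radiation, in which replication genes were higher and p53 targets lower in OE. By edgeR 2107 genes were called, 921 higher and 1186 lower. Siglech was at 5.15 ± 1.51, Cx3cr1 at 4.74 ± 1.2, Xcr1 at 4.52 ± 1.26 and Clec9a at 4.35 ± 1.19, and Polq and Parp1 at 1.96 ± 0.53 and 0.96 ± 0.21. Cdkn1a was at -1.42 ± 0.38 (adjusted p = 0.023), Trim63 at -8.38 ± 2.31 and the myogenic factor gene Myog at -6.81 ± 1.94. Replication genes rose in 24 of 34 (33 adjusted over the list alone) and p53 targets fell in 13 of 37 (13 adjusted over the list alone), at camera adjusted p = 3.35e-16 and 0.000117, both adjusted p = 0.723 with an estimated correlation. Dendritic cell markers rose in 6 of 16 and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.000858, adjusted p = 0.723 with an estimated correlation). No gene of the 22 in the muscle list was called by edgeR, over all genes or over the list alone (camera adjusted p = 0.116). By their codes the 3 written OE IR tumours are olaparib tumours without radiation (EO, EO and O), and the 3 written NC IR tumours are irradiated (IO, I and I). The count was 682, 634 and 688 without written OE IR replicates 1, 2 and 3, 1038, 1042 and 526 without written NC IR replicates 1, 2 and 3, and 4250 without written NC IR+olaparib replicate 1.

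Olaparib, averaged over both cell lines and both radiation settings, left every tested gene short of the threshold by code. Polq was at -0.27 ± 0.28 (adjusted p = 0.786), Parp1 at -0.22 ± 0.12 (adjusted p = 0.655), Lig3 at -0.08 ± 0.09 (adjusted p = 0.822), Cdkn1a at 0.11 ± 0.12 (adjusted p = 0.787) and Mki67 at -0.25 ± 0.29 (adjusted p = 0.801). Without NC IR replicate 3 Polq was at 0.01, Parp1 at -0.13, Cdkn1a at 0.04 and Mki67 at 0. Without OE IR+olaparib replicate 2 Polq was at -0.15 and Mki67 at -0.13. By edgeR 0 genes were called (1270 at an unadjusted p under 0.05, 1 by DESeq2), and under the written label 0 (437 and 1). The type I interferon list had a median of 0.31 with 31 of 32 members above 0 (camera adjusted p = 7.57e-10, adjusted p = 0.399 with an estimated correlation). Fibroblast markers had a median of 1.11 and 12 of 20 called adjusted over the list alone (camera adjusted p = 3.82e-07, adjusted p = 0.399 with an estimated correlation). In OE IR+olaparib replicate 2 the 50 highest genes, led by collagens, took 25.56% of counts. Without it the fibroblast median was 0.30 and 0 of 20 were called by edgeR adjusted over the list alone (camera adjusted p = 2.39e-05, adjusted p = 0.346 with an estimated correlation).

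Within single strata, olaparib against sham called 0 genes in NC tumours (1602 at an unadjusted p under 0.05, 26 by DESeq2) and 0 in OE tumours (340 and 3), both by edgeR. Parp1 was at -0.32 ± 0.25 (adjusted p = 0.708) in NC and -0.01 ± 0.25 (adjusted p = 1) in OE, and Mdm2 at 0.61 ± 0.38 (adjusted p = 0.618) and 0.02 ± 0.38 (adjusted p = 1). In NC, Parp1 was at -0.55 and -0.09 without NC olaparib replicates 1 and 2, and Mdm2 at 0.26 without NC olaparib replicate 2 and 0.35 without NC sham replicate 3. Written groups gave 0 (1867 and 205) and 0 (603 and 7). Without written NC IR+olaparib replicate 1 the NC count was 89, without written NC olaparib replicate 1 it was 5, and without written NC sham replicate 2 it was 1.

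Adding olaparib to radiation called 0 genes in NC tumours by edgeR (625 at an unadjusted p under 0.05, 3 by DESeq2) and 0 in OE tumours (2219 and 728). In NC the type I interferon list had a median of 0.65 with 32 of 32 members above 0 (camera adjusted p = 2.71e-16, adjusted p = 0.586 with an estimated correlation), and Mdm2 was at 0.32 ± 0.38 (adjusted p = 1), or 0.15 without NC IR replicate 3. In OE, fibroblast markers had a median of 3.25 and 19 of 20 called adjusted over the list alone (camera adjusted p = 9.5e-11, adjusted p = 0.558 with an estimated correlation). Pdcd4 was at 1.2 ± 0.41 (adjusted p = 0.162) and Polq at -0.54 ± 0.55 (adjusted p = 0.691). Without OE IR+olaparib replicate 2 the fibroblast median was 0.31 and edgeR called 0 of 20 adjusted over the list alone (camera adjusted p = 0.0252, adjusted p = 0.879 with an estimated correlation). Pdcd4 was then at 0.32 ± 0.30 (adjusted p = 1) and Polq at -0.06. Pdcd4 was called as higher without OE IR+olaparib replicates 1 and 3 (adjusted p = 0.0376 and 0.0305). Polq was at -0.94 without OE IR+olaparib replicate 3. The OE count was 1016 without OE IR+olaparib replicate 1 and 1268 without replicate 3, each of which leaves the collagen-led tumour as 1 of 2 in its group.

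In the written groups the same step called 422 genes in NC, 181 higher and 241 lower, and 0 in OE by edgeR (2276 at an unadjusted p under 0.05, 261 by DESeq2). Higher were the matrix genes Mmp13 at 5.72 ± 1.22 and Fbn2 at 5.88 ± 1.55 and the signalling gene Wnt2 at 5.73 ± 1.47, and lower the macrophage genes Vsig4 at -3.70 ± 0.72 and Fcna at -2.79 ± 0.54. Fibroblast markers rose in 8 of 20 (17 adjusted over the list alone, camera adjusted p = 6.53e-06, adjusted p = 0.825 with an estimated correlation). Without written NC IR+olaparib replicate 1, the collagen-led tumour, 3 of 20 rose (median -0.53 in place of 3.36, camera adjusted p = 0.69). Mmp13, Fbn2 and Wnt2 were then at 1.48 ± 0.61, 1.54 ± 1.13 and 1.15 ± 1.00 and not called (adjusted p = 0.102, 0.368 and 0.455), while Vsig4 and Fcna stayed called. The NC count was 3001 without written NC IR+olaparib replicate 1, 65, 73 and 19 without written NC IR replicates 1, 2 and 3, and 634 without NC olaparib replicate 2. It was 237, 232 and 215 without written OE sham replicates 1, 2 and 3, 277 and 227 without OE IR replicates 1 and 3, 254 without OE IR+olaparib replicate 2 and 277 without OE olaparib replicate 1. The OE count was 568 without written NC IR+olaparib replicate 1, 10 without OE olaparib replicate 2 and 1 without NC sham replicate 2.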

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

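The tests of list changes between the cell lines were planned, and the tests of what lies behind the unequal radiation calls were chosen only after the results were seen. For 16 gene lists the effect of radiation differed between OE and NC tumours by camera at its preset correlation, in the test of the radiation effect in OE minus that in NC by code (3 tumours per group). With an estimated correlation none of the 16 passed, at adjusted p = 0.807 to 0.859, and by fry none passed, at adjusted p = 0.469 to 0.701. Further up in OE means here that the radiation effect was higher in OE than in NC. A smaller fall in OE also gives this, so it need not be a rise after radiation. Further down likewise need not be a fall. Lists further up in OE were ribosomal proteins (median difference 0.66, adjusted p = 9.36e-07), oxidative phosphorylation (0.59, adjusted p = 9.36e-07), DNA replication (0.64, adjusted p = 6.89e-05), type I interferon (0.83, adjusted p = 7.88e-05) and interferon gamma with antigen presentation (0.79, adjusted p = 0.000196). Further up in OE too were hypoxia response (0.50, adjusted p = 0.0168), erythroid cells (2.61, adjusted p = 0.0193), T cells (1.17, adjusted p = 0.0193), mitosis (0.41, adjusted p = 0.0242), cGAS-STING and chemokines (0.78, adjusted p = 0.0248), macrophages (0.59, adjusted p = 0.0452) and senescence-associated secretion (0.30, adjusted p = 0.0475). Further down in OE were skeletal muscle (-5.77, adjusted p = 7.8e-05), the literature targets of miR-21-5p (-0.58, adjusted p = 0.000138), endothelium (-1.60, adjusted p = 0.000526) and adipocytes (-2.99, adjusted p = 0.0168). These list differences were not refitted with single tumours left out. The NC medians of muscle and ribosomal genes that enter them moved without single NC tumours, as given above.

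Radiation alone called 1659 genes in NC and 41 in OE by code. This order did not hold in every fit, since edgeR called 0 in NC and 2106 in OE with only the compared groups (2886 and 638 by DESeq2 on all groups), and 10 and 1093 without the 3 libraries of unlike composition. That last fit left out NC IR replicate 1 and NC sham replicate 3 but no compared OE tumour, so the cell lines differed in tumour number. A candidate explanation of the higher NC count in the fit of all libraries is 1 NC IR tumour with 2.154% of its counts in muscle genes, since 2 genes were called without it. The count was also 3 without NC sham replicate 3, and 271, 269 and 3733 without NC sham replicate 1, NC IR replicate 2 and NC IR replicate 3, so more than that tumour bears on it. The biological alternative, that miR-21-5p alters the response, found 0 genes called by edgeR in the test of the difference (2992 at an unadjusted p under 0.05, 603 by DESeq2), and 737 without OE IR+olaparib replicate 2. With 3 tumours per group the 2 explanations cannot be told apart.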

How the results depend on the processing

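Sample quality weights, fits without the 3 libraries of unlike composition and fits without the collagen-led tumour were chosen after the data were seen, the other alternatives before. The radiation average by code had 5504 to 9116 calls in every alternative run, and overlap of the genes called was not compared. No list past camera in the OE and radiation averages changed direction without each of the 3 unlike libraries in turn. Genes refitted without each compared library were the largest changes and fixed genes of both averages, OE against NC after radiation and radiation in OE. For radiation in NC, called genes refitted this way were Cx3cr1, Fdps, Cdkn1a, Mdm2 and Ccng1. No called gene among all these changed direction. Genes short of the threshold did, among them Polq and Mdm2 in the OE average. With 3 tumours per group and one shared estimate of spread, contrasts of 2 groups depended on single libraries and on the tool, and the cause of the moved counts was not tested beyond the smaller number of libraries in some fits.

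By code the DESeq2 test called 376 (OE against NC, sham), 794 (after radiation), 2886 (radiation in NC), 638 (radiation in OE), 26 and 3 (olaparib in NC and OE), 3 and 728 (olaparib added to radiation in NC and OE), 603 (difference of radiation effects), 628 (OE average) and 1 (olaparib average). Without the filter the counts were 6 (OE against NC after radiation), 799 (radiation in NC), 21 (radiation in OE) and 39 (OE average), and DESeq2 size factors gave 124 for the OE average. With only the compared groups in the fit they were 1 (OE against NC, sham), 0 (after radiation), 0 (radiation in NC), 2106 (radiation in OE) and 9 (difference). Limma voom with sample quality weights gave 1006, 3279, 5851, 5660, 27, 2903 and 2726 for OE against NC in sham, after radiation, radiation in NC, in OE, olaparib in OE, the difference and the OE average. This setting changed the test as well as the weights, and no voom fit without weights was run, so the 2 cannot be told apart. Without the 3 unlike libraries the counts were 288 (OE against NC after radiation), 10 (radiation in NC), 1093 (radiation in OE), 2 (difference) and 837 (OE average). Without the collagen-led tumour they were 23, 989, 3856, 397 and 737 for OE against NC in sham, after radiation, radiation in NC, in OE and the difference. Leaving out 1 compared library gave 0 to 677 (OE against NC after radiation), 2 to 3733 (radiation in NC), 0 to 136 (radiation in OE), 0 to 1268 (olaparib added in OE), 0 to 1 (difference), 15 to 838 (OE average) and 5504 to 7540 (radiation average).

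Under the written label DESeq2 called 84 (OE against NC, sham), 3355 (after radiation), 302 (radiation in NC), 2 (radiation in OE), 205 and 7 (olaparib in NC and OE), 1262 and 261 (olaparib added in NC and OE), 7 (difference), 468 (OE average), 2502 (radiation average) and 1 (olaparib average). The coded groups gave 14, 1659, 41, 0, 75 and 6483 for OE against NC after radiation, radiation in NC, in OE, olaparib added in NC, the OE average and the radiation average. Without the filter radiation in NC had 0 and olaparib added in NC 256. With only the compared groups counts were 5163 (OE against NC after radiation), 0 (radiation in NC), 0 and 1549 (olaparib added in NC and OE) and 4 (difference). The radiation average had 406 with DESeq2 size factors and 0 with additive factors, which gave 1 for the olaparib average. Leaving out 1 compared library gave 526 to 1042 (OE against NC after radiation), 0 to 5 (radiation in NC), 0 to 5 (olaparib in NC), 19 to 3001 (olaparib added in NC), 0 to 282 (OE average) and 0 to 2752 (radiation average).

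Camera at the preset correlation called 185 lists over the 12 comparisons by code and 198 under the written label, 0 and 0 with an estimated correlation and 23 and 4 by fry. Seed sites of 8 bases gave 0.053 for the OE average by code, now past the threshold (camera adjusted p = 0.0442, p = 0.183 with an estimated correlation). Genes with such a site were thus higher in OE, the opposite of repression by miR-21-5p. No control orders were run for sites of 8 bases. Without the collagen-led tumour 5 lists no longer passed camera at the preset correlation, fibroblasts, NF-kB and pericytes in the OE average (adjusted p = 0.428, 0.0742 and 0.137) and mast cells and muscle in the radiation average (adjusted p = 0.0582 and 0.123). In the written groups the fibroblast list for olaparib added in NC no longer passed (adjusted p = 0.69), and Mmp13, Fbn2 and Wnt2 were no longer called. Among values of single genes and lists the DESeq2 test made 4 stronger and 5 weaker, a fit on the compared groups 4 and 17, no filter 21 weaker, additive factors 5 weaker and an estimated correlation 33 weaker.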

Other observations

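Tests in this part of sterol synthesis, of the labels within strata and of the collagen-led tumour were chosen only after the results were seen, and the regroupings of tumours were planned. Genes of sterol synthesis fell with radiation beyond those already named. A list of 23 genes of the pathway and its control was written after several members, Cyp51, Fdps and Sqle among them, had been seen among the largest falls, and 21 of its members fell in the radiation average by code, with a median of -1.45. Hmgcs1, which feeds the mevalonate pathway, was at -1.79 ± 0.15 (edgeR adjusted p = 1.19e-06), and Srebf2, the transcription factor that drives the set, at -1.45 ± 0.17. Ebp and Tm7sf2 were not called, at -0.10 ± 0.07 (adjusted p = 0.258) and -0.08 ± 0.14 (adjusted p = 0.695). Among the 17 members not named before the list was written 15 fell (camera p = 0.00374 with an estimated correlation, 12 tumours against 12). These 17 share their regulation with the genes that led to the list, so a fall of the pathway as a set is a hypothesis from the same data. Of the same 17, 15 fell in NC tumours given radiation alone, with a median of -1.22 (camera p = 0.00298 with an estimated correlation). Without NC IR replicate 1 that whole contrast called 2 genes, and few without NC sham replicate 3, so most of these 15 calls depend on single tumours. In OE tumours none of the 17 was called by edgeR, and 14 lay below 0 with a median of -0.65 (camera p = 0.0387 with an estimated correlation). The 17 leave out Hmgcs1 and Insig1, named above because they were called in OE. The lack of calls among the 17 in OE is therefore no contrast with NC. Of all 23 genes 2 were called as lower in OE and 21 in NC. For the same 17 the radiation effect in OE minus that in NC had a median of 0.65, a smaller fall in OE. Camera gave p = 0.0682 with an estimated correlation and p = 2.56e-06 at the preset one, and fry gave p = 0.0158. The tests thus differ, and this difference was not refitted with single tumours left out.

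The p53 target list followed the coded identifier and not the written label. Within tumours of the same code, those written as irradiated were 0.06 higher on the mean log2 CPM than the others (permutation p = 0.42), where a true written label would give a clear rise. Within tumours of the same written label, those coded as irradiated were 0.464 higher (permutation p = 1.0e-05, the smallest these permutations can give), on 8 tumours irradiated by both, 4 by the written label alone, 4 by code alone and 8 by neither. A candidate explanation is that the written treatment was attached to the wrong tumours and that the code gives the groups, which these values are consistent with. Cell line and olaparib by code cannot be checked in this way, since neither separated the libraries in the check of the labels. By code the pseudo-F was 1.21 (permutation p = 0.26) for cell line and 0.85 (permutation p = 0.48) for olaparib. By the written label it was 1.80 (permutation p = 0.098) and 0.40 (permutation p = 0.96). For cell line the written value was thus the larger, and neither reading of it is favoured by this check.

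OE IR+olaparib replicate 2 by code differed from the other 2 tumours of its group. Col3a1, Col1a1 and Col1a2 were its most abundant genes, Col3a1 with 3.51% of counts. Fibroblast markers were 4.49 higher on the log2 scale, muscle 6.28, adipocytes 3.52, pericytes 2.97 and endothelium 2.35, whereas mitosis genes were at -4.38, T cells at -0.17, macrophages at -0.44 and basal squamous genes at 0.03. Dilution by its 50 highest genes would lower other genes by -0.22, and replication genes were at -2.25, which argues against a few genes taking the counts as the whole cause. Its total of 39187776 counts (39.19 in units of 1000000) lies within the range of the other libraries, 37099055 to 40004502, which argues against depth. More connective tissue in the piece of tumour taken may account for it, as a hypothesis from the 4.49 rise in fibroblast markers, and a change made by the treatment in this 1 animal was not tested.

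Chance could be weighed by regrouping the tumours where 12 stood against 12 or 4 groups entered a contrast, over 41 splits with the real one. By code 1 of 41 splits called as many genes as the real one for the radiation average (6483, at most 0 in any other) and for OE against NC (75, at most 0). A share of 1 in 41 is the smallest these splits can give. The written radiation average below reaches it with 1 called gene, so the share does not exclude chance. For the olaparib average and for the difference of radiation effects all 41 splits called as many as the real count of 0, with at most 0 and 2 in another split. Under the written label the radiation average called 1 gene against at most 0 in the other splits (1 of 41), and the other 3 contrasts of this kind had a real count of 0, reached by 41 of 41, with at most 667 in another split for the difference of radiation effects, 104 for the olaparib average and 0 for OE against NC. Other groupings could thus call 667 and 104 genes where the written one called 0. The split with 104 calls held tumours coded as irradiated on both sides, and what lies behind its count was not tested. The split with 667 calls, looked up after its count was seen, set 6 tumours coded as unirradiated against 5 coded as irradiated and 1 coded as sham.

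For contrasts of 3 tumours with 3 there are 10 splits, too few for a share under 0.05. By code the real counts and the highest others were 14 and 0 for OE against NC after radiation, 1659 and 1267 for radiation in NC and 41 and 0 for radiation in OE, each reached by 1 of 10. The split with 1267 calls crossed the code, with NC IR replicates 1 and 2 and NC sham replicate 3 on one side. Its other side held NC IR replicate 3 and NC sham replicates 1 and 2, and what lies behind its count was not tested. The contrasts with a real count of 0 were reached by 10 of 10, with at most 1 in another split. Under the written label they were 2107 and 0 for OE against NC after radiation and 5 and 0 for radiation in NC (1 of 10 each), and 422 and 2146 for olaparib added to radiation in NC (3 of 10). The 5 written contrasts with a count of 0 were reached by 10 of 10, with at most 1 in another split. The 2146 calls in another grouping exceed the 422 of the written one. That split, looked up after its count was seen, set the collagen-led tumour and NC IR replicates 1 and 2 by code against NC IR replicate 3, NC IR+olaparib replicate 1 and NC sham replicate 2, and what lies behind its count was not tested.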
